A study of Daphnia magna with 48 samples.

How the data were processed

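RNA from dissected guts of the water flea Daphnia magna was measured on 48 microarrays, 1 array per sample, in 16 groups named by the sample titles. Per the labels, total RNA had been extracted with Trizol and labelled with Cy3 by a low-input amplification kit, then hybridised to a custom 1-colour Agilent array for this species. The authors read the scans with Agilent Feature Extraction 10.5, whose processed signal is the spot brightness after background subtraction and detrending within the array. Per the file headers, the processed signal is an intensity on a linear scale, with no scaling between arrays and with dim spots set to a floor. The median spot signal and the median local background in the same files were deposited as intensity too. The deposited series table holds the intensity of the processed signal rounded to 3 significant digits, and each of its values lay within 0.498% of the scanner value.

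Each array carried 62976 spots, of which 59125 belonged to 51424 probes and 3851 were controls. The values were taken from the scanner files in R 4.3.3 with the data.table package, version 1.17.8. Spots marked as outliers in the scan were removed, the log2 processed signal was taken, and spots of the same probe were averaged. Each array was then scaled by subtracting its 75th percentile, computed over the 679 probes marked well above background on all 48 arrays. Values given below as log2 signal are on this scale, where 0 is the 75th percentile of those bright probes. A probe was tested when it was well above background on every array of at least 1 group, which kept 12872 probes, or 25% of them, and 73 of these had a missing value on some array.

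One linear model with a mean per group was fitted to all 48 arrays with limma 3.58.1, so that the groups shared an estimate of the spread, and was followed by empirical Bayes moderation. Each exposure was compared with the control group its title names, each high level with its low level, and the effect of each high exposure with the effect of starving through an interaction contrast. The 4 control groups were compared with a moderated F-test. All tests were two-sided, with Benjamini-Hochberg adjustment over the probes tested and a threshold of 0.05. Responses were also compared by the correlation of their log2 changes across probes, as a description with no p-value, since probes are not independent replicates. Responses that share control arrays are correlated by construction, so that correlation was also simulated with no true effect, 60 times from the residuals of these arrays, for 10 pairs that share controls and 6 that do not. The residuals were moved at random between all arrays, so the noisier arrays did not stay in their own groups and the simulated ranges are approximate. The same simulations gave the values without an effect for the size of the copper changes and for the cadmium probes in other exposures.

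The probe names matched none of the 28335 genes in the reference table, and the scanner files repeat the probe name where a gene name would stand. No probe therefore has a gene name, position or function here, and the 30 gene lists fixed in advance were not run. The fixed naming rule then took, per stressor, the 2 largest rises and the 2 largest falls in the high-level comparison among probes past the threshold whose treated and control arrays did not overlap, filling from the low level where the high level gave too few. A probe not well above background on any array of a group was given a fold bound, printed as at least that fold. The bound takes the mean of the other group, or of only its arrays well above background where that mean is nearer, and on each array of the undetected group the higher of the probe's own value and the lowest signal marked well above background.

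Arrays differed in brightness. The share of probes well above background ran from 2.23% to 27.01% with a median of 21.1%, and 4 arrays lay under 10%, called low-detection arrays here. The 6 slides carried 8 arrays each and were scanned on 3 days, with most groups spread over several slides. The number of arrays per group limits the precision, and the median 95% half-width of a log2 change between an exposure and its control ran from 1.47 to 1.67. Data were simulated with the spread of these arrays, independent noise for each probe and 200 of the 12872 probes changed. The same steps called 24.5% of 4-fold changes and 67.6% of 16-fold changes in the copper high comparison, and 11.8% of its simulated calls were false. The false share was 29.6% for starving, 22.6% for the half-food group, 2.9% for cadmium high and 0.2% for fluoranthene high, and 5.3% for copper high when all arrays were given equal spread. These shares depend on the 200 changed probes and the independent noise, so they are not the false shares of the real lists. The p-values measure only the spread between these samples, which may be technical. The series text gives 5 replicates per treatment, 3 of them drawn at random for hybridisation, and does not say whether they were separate cultures.

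Alternatives fixed before the data were examined were normexp background correction with an offset of 50, quantile normalization, no filter on dim probes, the replicate number as a block, a fit to the arrays of each experiment alone, the series table, slide as a block, and leaving out each array in turn. The planned normexp correction named the mean spot signal, which the files do not hold, so the median spot signal was used. Chosen after seeing the data were array weights estimated by limma, scaling to the 75th percentile of all probes, and fits without the 4 low-detection arrays, without slide 6 and without both. With a median of 21.1% of probes well above background, the 75th percentile of all probes falls on dim probes on most arrays. Scaling to all probes thus largely aligns dim signal. Arrays with the same replicate number were compared for shared deviations, and 18 of 45 pairs had a correlation over 0.1 with a median of 0.016, so the numbers were not treated as pairing the arrays.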

Results

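Gene expression was measured in the gut of Daphnia magna, a freshwater crustacean that filters algae from the water, after exposure to chemicals that inhibit feeding or after food shortage. The exposures were cadmium and copper, which are metals, fluoranthene, a polycyclic aromatic hydrocarbon, cyhalothrin, a pyrethroid insecticide, and Planktothrix, a filamentous cyanobacterium. The series text names the toxin anatoxin a where the titles name Planktothrix, and the titles are followed here. Each exposure was given at a high and a low level, set by feeding inhibition, and there were 3 food levels, called full food, half-food and starving. Of the 16 groups, 14 had 3 arrays, the low cadmium group had 2 and the cadmium control group had 4. The controls were 3 arrays shared by copper and Planktothrix, 3 shared by cyhalothrin and fluoranthene, the 4 cadmium controls, and the full-food group for the food levels. The cadmium descriptions give the numbers 32 for the high level and 8 for the low level, without a unit. The copper descriptions give no concentration, and those of the low level carry the code H2, which the labels do not explain, so the copper levels rest on the titles alone.

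The share of the 51424 probes well above background had a median of 21.1% per array. It was lowest on cadmium control replicate 5 at 2.23%, followed by Planktothrix low replicate 2 at 5.69%, cyhalothrin low replicate 4 at 6.21% and copper and Planktothrix control replicate 1 at 7.42%. One slide, slide 6, differed from the others in its control spots. Its brightest added control transcript had a median log2 signal of 11.82, against 17.39 on the other slides, while the 99th percentile of its negative controls was higher, with a median of 831.4 against 134.9. It held both starving replicates 2 and 5, both fluoranthene high replicates 2 and 5, and 4 arrays of other groups. Probes are named by their array identifiers, since no gene name could be joined to them. All 12872 probes that passed the signal filter were tested with limma in each comparison.

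**Figure D1:**
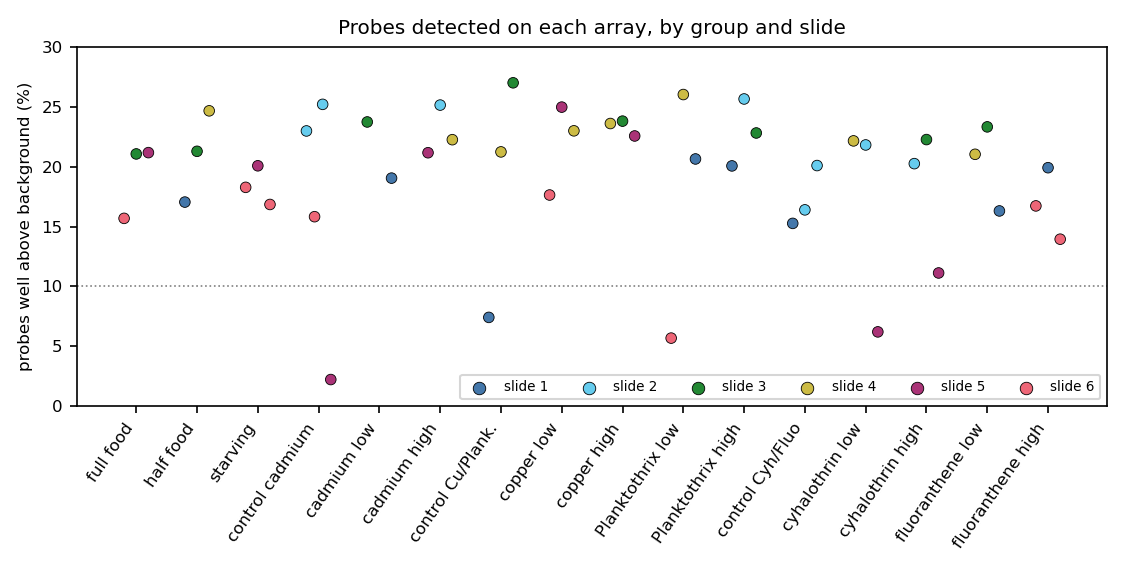
Percent of the 51424 probes well above background on each of the 48 arrays (vertical axis, percent), by group, with 1 point per array. Values run from 2.23% to 27.01%, and 4 arrays lie under 10%.

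Cadmium raised a small set of probes steeply. The signal of CUST_14595_PI429715507 rose from -5.86 ± 1.51 (SD, n = 4 controls) to 1.07 ± 0.33 (SD, n = 3) at the high level, a log2 change of 6.93 ± 0.91 (SE, adjusted p 1.43e-05), or 122-fold. CUST_33943_PI429715507 was well above background on all 3 exposed arrays at -1.06 ± 0.96 (SD) and on none of the 4 controls, and was at least 57.9-fold higher (limma adjusted p 0.0101). Among the falls, CUST_86743_PI429715507, well above background on 1 of the 3 exposed arrays, decreased by 4.06 on the log2 scale (SE 0.70, limma adjusted p 0.000939, n = 3 against 4). CUST_76174_PI429715507 was not well above background on any exposed array and was at least 4.52-fold lower (limma adjusted p 0.000512). The call of CUST_14595_PI429715507 was kept under all 19 alternatives, with log2 changes from 6.32 to 7.70. It was well above background on 3 of the 4 controls, so its fold is approximate. CUST_33943_PI429715507 fell below the threshold in 7 of them, 4 with 1 array left out, with an adjusted p of up to 0.286, CUST_86743_PI429715507 in 2 and CUST_76174_PI429715507 in 4.

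The cadmium comparison asked how the gut responds to the metal at each feeding-inhibition level. At the high level 80 probes passed the threshold, 55 higher and 25 lower, with 884 at an unadjusted p under 0.05. Treated and control arrays did not overlap for 55 of the risen and 24 of the fallen probes, where chance gives 5.7% of all probes and 8.4% of all tested probes had none. At the low level 9 probes rose and 2 fell, with 439 at an unadjusted p under 0.05, and all 11 changed the same way at the high level. CUST_14595_PI429715507 rose there too, by a log2 change of 6.94. No probe differed between the levels by limma, with 205 at an unadjusted p under 0.05. The median log2 change over all tested probes was 0.02 at the high level and -0.24 at the low level, and relative to it the risen probes at the low level changed by a median of 4.50 and the fallen by a median of -4.42. With slide as a block the high-level count was 104.

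The high-level count was 230 without cadmium control replicate 5, 44 without cadmium high replicate 1 and 40 without cadmium high replicate 4. The low-level count was 17 without cadmium control replicate 5, 5 without cadmium low replicate 2 and 59 without cadmium low replicate 3, where the 1 low-level array left was assumed to vary like the other groups. The count between the levels was 45 without cadmium low replicate 3. Quantile normalization gave 143 higher and 16 lower at the high level, and scaling to all probes gave 127 and 7.

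Copper changed many probes at both levels. CUST_63683_PI429715507 rose from -5.76 ± 1.13 (SD, n = 3 controls) to 0.80 ± 0.64 (SD, n = 3) at the high level, a log2 change of 6.56 ± 0.65 (SE, limma adjusted p 5.83e-09). CUST_89963_PI429715507 rose by a log2 change of 6.37 ± 1.01 (SE, limma adjusted p 4.87e-05), but its controls were spread at -5.88 ± 3.32 (SD, n = 3) and only 1 of them was well above background, so the size of this rise is uncertain. CUST_52615_PI429715507 fell by 7.44 (SE 0.98, limma adjusted p 2.68e-06), from -0.77 ± 1.22 (SD) to -8.21 ± 2.60 (SD), with 1 of 3 exposed arrays well above background. The size of this fall is uncertain too, with log2 changes from -8.94 to -5.53 over 18 alternatives. CUST_4414_PI429715507 was well above background on all 3 controls and on no high-copper array, and was at least 66.5-fold lower (limma adjusted p 5.83e-11). At the low level these 4 probes changed by 5.50, 5.63, -4.95 and -5.45 in the same order, the last with 1 of 3 exposed arrays well above background.

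Copper was compared with its control at both feeding-inhibition levels. At the high level 1323 probes rose and 369 fell, and at the low level 1552 rose and 351 fell, with 3687 and 3949 probes at an unadjusted p under 0.05. The median log2 change over all tested probes was 0.56 at the high level and 0.74 at the low level. Relative to it, the risen probes changed by a median of 1.30 and the fallen probes by a median of -3.37 at the high level, and by 1.21 and -3.38 at the low level. On this relative scale the changes of the first 3 probes above were 6.0, 5.81 and -8.00. Treated and control arrays did not overlap for 1274 of the risen and 364 of the fallen probes at the high level, and for 1291 and 338 at the low level. Chance gives 10%, and among all tested probes 38.7% did not overlap at the high level and 30.7% at the low level. With slide as a block 957 probes rose and 425 fell at the high level, and 834 and 408 at the low level.

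The share of copper calls that were increases depended on scaling. At the high level 78.2% rose, against 36.1% after quantile normalization (165 higher, 292 lower), 26.3% with scaling to all probes (71 higher, 199 lower) and 44.7% after normexp correction (192 higher, 238 lower). At the low level 81.6% rose, against 24.4%, 11.6% and 35.4% under the same 3 settings. Scaling to all probes rests mostly on dim signal. On copper control replicate 1 that percentile was a processed signal of 7.49, where the floor was 4.99. The calls made at the high level here and under 10 alternatives, those without slide 6 not among them, were 11 risen and 75 fallen probes, and at the low level 7 risen and 87 fallen. The high-level count was 383, 565 and 2892 without control replicates 1, 2 and 5, and 923, 652 and 851 without copper high replicates 3, 4 and 5. The low-level count was 391, 569 and 3004 without the same controls, and 873 and 717 without copper low replicates 4 and 5. No probe differed between the levels by limma, with 99 at an unadjusted p under 0.05.

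**Figure D2:**
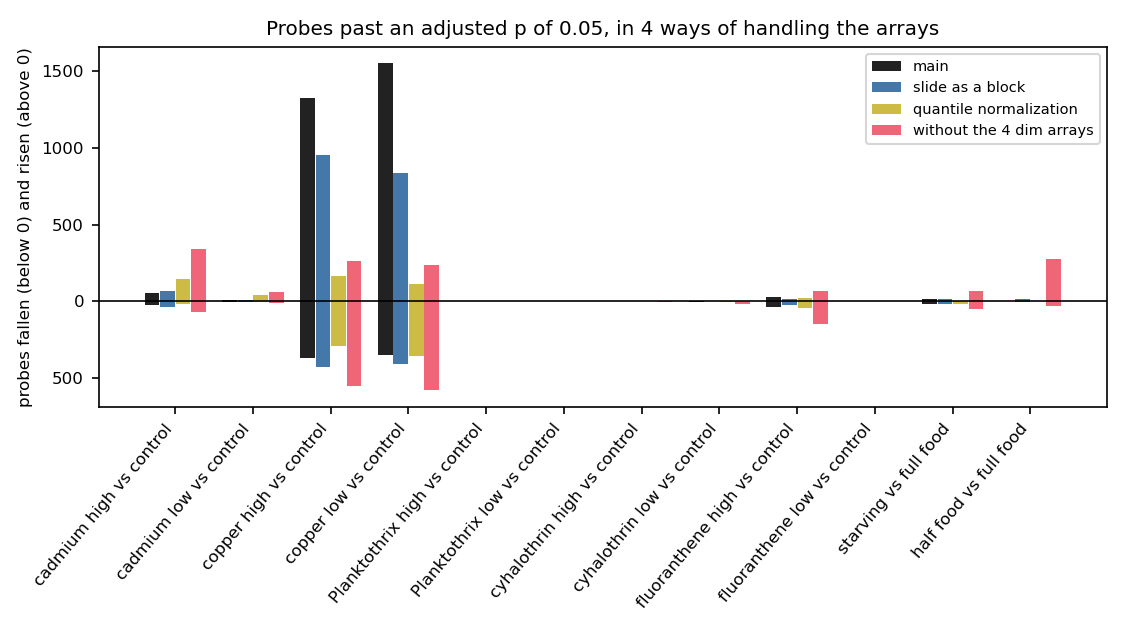
Number of probes higher (up) and lower (down) than control in each of the 12 comparisons (limma, adjusted p under 0.05). Bars show the main fit, slide as a block, quantile normalization and the fit without the 4 low-detection arrays. The last tested 14087 probes and the others 12872. In the main fit copper high has 1323 and 369, cadmium high 55 and 25, fluoranthene high 29 and 35, and starving 17 and 16.

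Planktothrix, tested against the control arrays that copper also used, gave no probe past the threshold by limma at either level. At an unadjusted p under 0.05 there were 1412 probes at the high level and 2757 at the low level, and the smallest adjusted p was 0.346 and 0.104. The median log2 change over all tested probes was 0.16 and 0.84. Planktothrix low replicate 2 had the highest signal floor of all arrays, at 206.23, with 76.2% of its spots at or near it. The floors of replicates 3 and 5 were 7.33 and 9.92. How much of the low-level shift comes from that array was not separated. Between the levels limma gave 0, with 404 at an unadjusted p under 0.05. Without control replicate 5 the counts were 817 at the high level and 1471 at the low level.

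Cyhalothrin gave 3 probes at the low level, named here from that level because the high level had none. CUST_36222_PI429715507 rose from -6.77 ± 0.70 (SD, n = 3) to -3.65 ± 0.91 (SD, n = 3), a log2 change of 3.12 ± 0.50 (SE, limma adjusted p 0.00373). CUST_100498_PI429715507 rose by a log2 change of 2.5 ± 0.41 (SE, limma adjusted p 0.00373), and CUST_2126_PI429715507 fell by 4.90 (SE 0.92, limma adjusted p 0.0251). All 3 low-level arrays lay beyond all 3 controls for each of them, as the naming rule requires. Low-level replicates 1 and 3 were unusually alike. Their correlation across probes was 0.9865, the highest of 49 pairs of arrays within groups, where the median was 0.868. The reason was not tested. Among all tested probes 15.9% did not overlap at this level, where chance gives 10%. Under 18 alternatives these calls were lost in 8, 5 and 13 in the same order. For CUST_2126_PI429715507 these included slide as a block (-4.97 ± 1.02, SE, adjusted p 0.0881), the fit without slide 6 and 5 of 6 fits with 1 array left out. At the high level limma gave 0 probes, with 587 at an unadjusted p under 0.05, and there were 734 at the low level. High against low gave 0 by limma, with 196 at an unadjusted p under 0.05. The low-level count was 0 without control replicate 1, 1 without cyhalothrin low replicate 1, and 5 without either cyhalothrin low replicate 3 or 4.

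Fluoranthene at the high level raised and lowered similar numbers of probes. CUST_14595_PI429715507, raised by cadmium as well, was well above background on all 3 exposed arrays at -2.74 ± 0.38 (SD) and on no control, and was at least 35.3-fold higher (limma adjusted p 0.000881). CUST_108943_PI429715507, well above background on 1 of 3 controls, rose by a log2 change of 5.30 ± 0.93 (SE, n = 3 and 3, limma adjusted p 0.0016). CUST_101160_PI429715507 fell from 1.49 ± 0.68 (SD) to -3.54 ± 0.44 (SD), a log2 change of -5.03 ± 0.65 (SE, limma adjusted p 5.16e-05). CUST_51722_PI429715507 fell by 3.58 (SE 0.67, limma adjusted p 0.00332), but with slide as a block its change was -2.69 ± 0.65 (SE, adjusted p 0.0686) and the call was lost. Slide 6 held 2 of the 3 exposed arrays. The calls were lost without it, but that fit leaves 1 exposed array, so the loss does not show that the changes went away. Under 18 alternatives the 4 calls were lost in 2, 5, 1 and 6 in the order named. Over the same alternatives, that fit among them, their log2 changes ran from 3.51 to 6.46, 3.30 to 5.90, -5.77 to -4.65 and -4.32 to -2.69.

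In all, 29 probes rose and 35 fell with fluoranthene at the high level, with no overlap between exposed and control arrays for any of them, where chance gives 10% of all probes and 23.5% of all tested probes had none. There were 1337 probes at an unadjusted p under 0.05, and the median log2 change over all tested probes was 0.39. Relative to it the risen probes changed by a median of 2.61 and the fallen by -3.02. With slide as a block the count was 37, and without slide 6, which leaves 1 exposed array, it was 1. At the low level limma gave 0, with 106 at an unadjusted p under 0.05. Between the levels 5 probes were lower at the high level and none higher, with 1212 at an unadjusted p under 0.05. They were CUST_101160_PI429715507 at -3.72, CUST_41163_PI429715507 at -2.77, CUST_30186_PI429715507 at -2.60, CUST_109899_PI429715507 at -2.36 and CUST_37035_PI429715507 at -2.01 on the log2 scale, 4 of them named after their values were seen.

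The share of fluoranthene calls that rose was 45.3%, against 33.3% after quantile normalization (20 higher, 40 lower) and 77.8% with scaling to all probes (7 higher, 2 lower). Under the 10 alternatives counted for cadmium, 1 of the 64 high-level calls was kept in all, a fall. The high-level count was 35, 32 and 40 without control replicates 1, 4 and 5, and 29 and 40 without fluoranthene high replicates 2 and 5. The count between the levels was 2 without fluoranthene high replicate 2 and 0 without fluoranthene high replicate 5, low replicate 2 or low replicate 3.

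Starving lowered CUST_16607_PI429715507 from 0.55 ± 0.21 (SD, n = 3 full-food arrays) to -6.07 ± 0.45 (SD, n = 3), a log2 change of -6.62 ± 0.89 (SE, limma adjusted p 0.000145). CUST_44026_PI429715507 fell by 3.74 (SE 0.61, limma adjusted p 0.00236). CUST_76717_PI429715507 rose by a log2 change of 4.05 ± 0.79 (SE, limma adjusted p 0.0114), and CUST_108698_PI429715507, well above background on 1 of 3 full-food arrays, by 3.66 ± 0.82 (SE, limma adjusted p 0.037). Relative to the median log2 change of all tested probes, which was 0.88, these changes were -7.50, -4.62, 3.17 and 2.78 in the same order. At the half-food level CUST_79003_PI429715507 rose by a log2 change of 2.36 ± 0.42 (SE, limma adjusted p 0.0264), named after its value was seen. Under 18 alternatives the calls of CUST_16607_PI429715507, CUST_44026_PI429715507, CUST_76717_PI429715507, CUST_108698_PI429715507 and CUST_79003_PI429715507 were lost in 1, 3, 8, 10 and 9. The 1 loss of CUST_16607_PI429715507 was in the fit without slide 6, which also lost CUST_76717_PI429715507 and CUST_108698_PI429715507. Slide 6 held 2 of the 3 starving arrays, so that fit leaves 1. Over the 18 alternatives, that fit among them, the log2 change of CUST_16607_PI429715507 ran from -7.76 to -6.09. With 1 array left out, 3 of 6 fits lost CUST_76717_PI429715507, 4 lost CUST_108698_PI429715507 and 4 lost CUST_79003_PI429715507.

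These comparisons asked how the gut responds to less food. Starving against full food gave 17 risen and 16 fallen probes, with 2270 at an unadjusted p under 0.05 and no overlap for 15 and 16 of them. Chance gives 10%, and 16.6% of all tested probes did not overlap. The half-food level gave 1 risen probe, with 1020 at an unadjusted p under 0.05, and 22 probes passed with slide as a block. Starving against half-food gave 0 by limma, with 1812 at an unadjusted p under 0.05. With slide as a block the starving count was 35, and without slide 6, which leaves 1 starving array, it was 4. The share that rose was 51.5%, against 15.8% after quantile normalization (3 higher, 16 lower) and 23.1% with scaling to all probes (3 higher, 10 lower). Under the 10 alternatives counted for cadmium, 1 of the 33 starving calls was kept in all, a fall.

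The starving count was 1878, 13 and 15 without full-food replicates 1, 2 and 5, and 10, 641 and 2 without starving replicates 2, 4 and 5. The half-food count was 498 without full-food replicate 1, and 0 without full-food replicates 2 or 5 or half-food replicates 2 or 3.

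**Figure D3:**
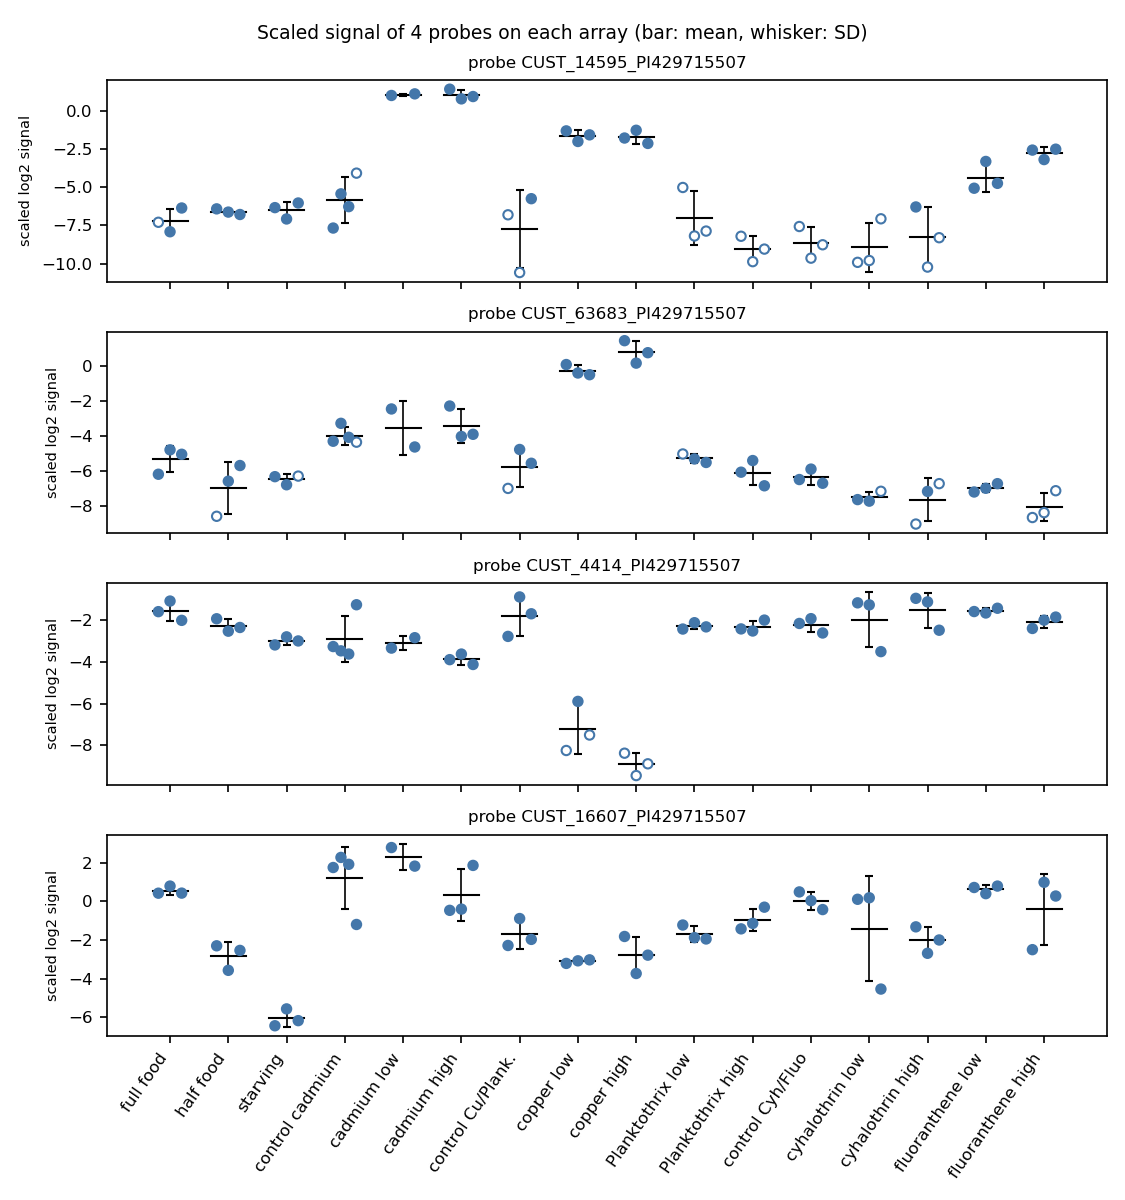
Scaled log2 signal (vertical axis) of 4 probes on every array by group. Filled points are well above background and open points are not, bars are group means and whiskers are SD. CUST_14595_PI429715507 lies at 1.07 ± 0.33 with cadmium high and -5.86 ± 1.51 in its controls, and CUST_16607_PI429715507 at -6.07 ± 0.45 in starving and 0.55 ± 0.21 with full food.

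The metals shared part of their response, measured against separate control arrays. Of the 80 probes called with cadmium high, 46 were called in the same direction with copper high and 1 in the opposite direction, where 6.37 would fall together if the calls were independent. The correlation of the changes across the tested probes was 0.504 (Spearman 0.482), where 60 simulations without a true effect gave 95% of values between -0.672 and 0.426. That range is approximate, since the simulations did not keep the noisier arrays in their groups. Among named probes, CUST_14595_PI429715507 had log2 changes of 6.0 and 6.10 at the high and low copper levels, whose size is uncertain because only 1 of the 3 copper controls was well above background (-7.71 ± 2.55, SD), and CUST_36222_PI429715507 had 3.75 and 4.55 with cadmium high and low, 3.71 and 3.10 with copper high and low, and 3.64 with fluoranthene high. With fluoranthene high, 12 of the cadmium high probes were called in the same direction, where independence gives 0.192. The correlation of those responses across the tested probes was nevertheless -0.174 (Spearman -0.181). With starving, 9 of the cadmium high probes were called alike, where independence gives 0.104, so shared calls were not particular to the metals.

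Responses that use the same control arrays are correlated even without an effect, and the simulations gave mean correlations from 0.34 to 0.506 for 10 such pairs. For 2 pairs the measured correlation lay above the simulated 95% range. Copper high and low reached 0.894 (range -0.117 to 0.862), with 1401 probes called alike, and cadmium high and low reached 0.742 (range -0.25 to 0.736). Neither excess decides, because the simulations did not keep noisy arrays in the shared controls. Deviations from the group mean had an SD of 1.17, 1.00 and 1.12 on the copper controls, and 0.61, 0.58 and 0.58 on copper high. On cadmium control replicate 5 the SD was 1.33. Noisier controls raise the correlation without an effect. The other 8 pairs were not above the simulated range, among them copper high and Planktothrix high at 0.806 (range -0.034 to 0.827) and Planktothrix high and low at 0.784 (range -0.074 to 0.824). Fluoranthene high and low at 0.213, starving and half-food at 0.325 and cyhalothrin high and fluoranthene high at 0.282 lay below their simulated means of 0.47, 0.506 and 0.477.

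The study set toxic feeding inhibition beside food shortage, so each high-level response was compared with that of starving, which shares no arrays with it. The correlation across probes with the starving response was 0.476 for fluoranthene high, 0.314 for Planktothrix high, 0.268 for copper high, 0.137 for cadmium high and -0.12 for cyhalothrin high. Each lay within the 95% range that the simulations gave without a true effect, which for fluoranthene was -0.521 to 0.51 and for copper -0.6 to 0.355. Probes called in the same direction in both were 15 for copper, 9 for cadmium and 7 for fluoranthene, where independence gives 2.21, 0.104 and 0.0818. With slide as a block the fluoranthene correlation was 0.136. Leaving out 1 array at a time, the correlations ran from 0.30 to 0.57 for fluoranthene, 0.06 to 0.53 for Planktothrix, 0.02 to 0.48 for copper, -0.08 to 0.32 for cadmium and -0.20 to 0.05 for cyhalothrin.

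Tested directly, the effect differed from that of starving for 177 probes with copper (40 more positive, 137 more negative), 5 with cadmium, 2 with fluoranthene and 1 with Planktothrix. For cyhalothrin limma gave 0, with 1450 at an unadjusted p under 0.05. The Planktothrix probe was CUST_16607_PI429715507, at 0.76 with Planktothrix and -6.62 with starving, a difference of 7.38. The fluoranthene probes were CUST_36222_PI429715507 and CUST_34026_PI429715507, with differences of 4.78 and 4.44. The cadmium probes were CUST_36222_PI429715507 at 4.89, CUST_101160_PI429715507 at 4.48, CUST_108823_PI429715507 at 3.70, CUST_95539_PI429715507 at 3.62 and CUST_34026_PI429715507 at 3.24, and those outside the naming rule were chosen after their values were seen. The copper count was 490 without full-food replicate 1, 98 without full-food replicate 5 and 266 without copper control replicate 5. Without full-food replicate 1 the counts were 102 for cadmium, 575 for cyhalothrin, 28 for fluoranthene and 16 for Planktothrix. The cadmium count was 12 without cadmium control replicate 5. It was 2 without full-food replicates 2 or 5, cadmium control replicate 2 or starving replicates 4 or 5, and 1 without cadmium control replicate 1 or any cadmium high array. The Planktothrix count was 0 without full-food replicates 2 or 5, control replicates 1 or 5, Planktothrix high replicate 4 or starving replicates 2 or 5, and the fluoranthene count was 4 without fluoranthene high replicate 4.

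**Figure D4:**
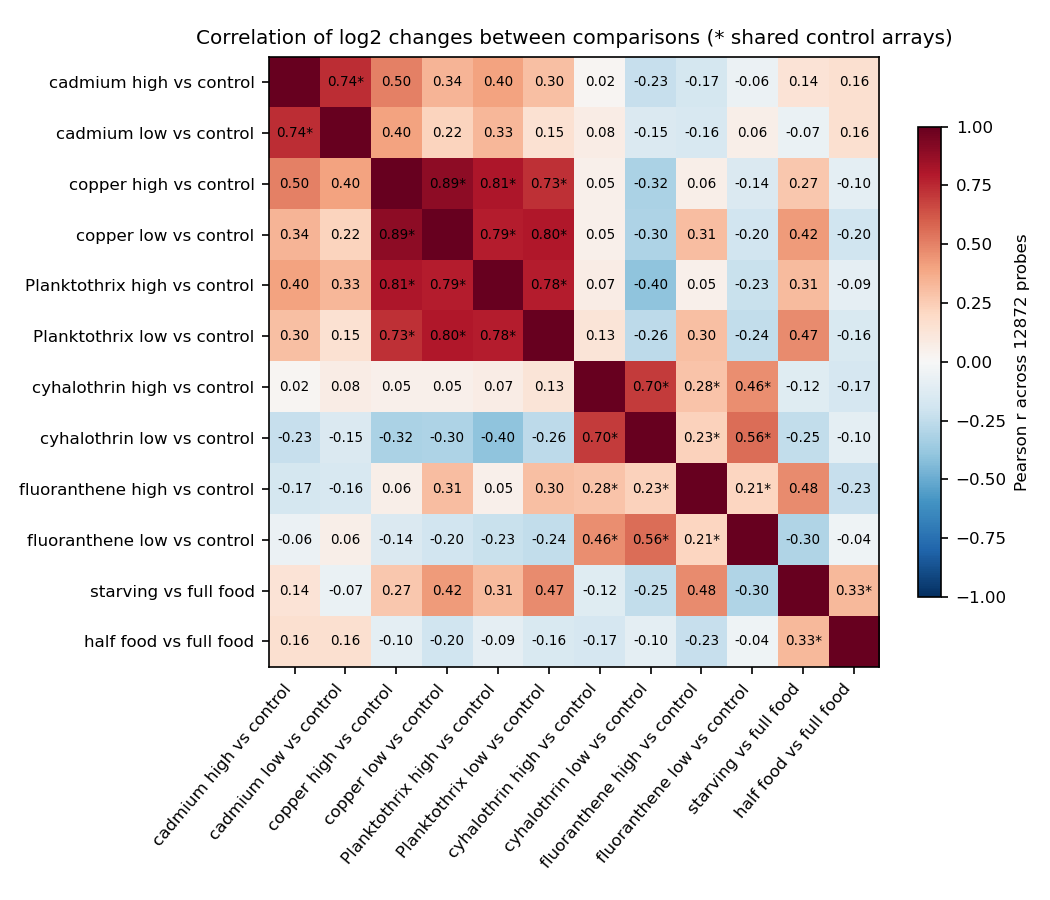
Pearson correlation across the 12872 tested probes between the log2 changes of each pair of comparisons. Copper high and low reach 0.894 with shared controls, and cadmium high and copper high reach 0.504 with separate controls.

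The 4 control groups, kept apart because the titles set each beside its own exposures, differed from each other at 617 probes (limma F-test), with 2641 at an unadjusted p under 0.05. The full-food group was the furthest from the others for 495 of the 617, with a median log2 difference of -2.36 among them, and the cadmium controls were the furthest for 81. The count was 1766 without full-food replicate 1, 3 without full-food replicate 2 and 75 without full-food replicate 5.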

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

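Chosen after the result was seen were the tests of the dim control array, of scaling and of slide on the share of copper increases, the fit without slide 6 for the fluoranthene correlation, and the tests of the fallen cadmium probes and of the cadmium probes readable on control replicate 5. The first of these was redone once with 25 risen and 25 fallen probes after a form with 4 fallen ones, and the second was run in 6 forms. The other tests in this part were fixed before their values were seen.

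Cadmium control replicate 5 stood apart. Its lowest processed signal was 113.89, where the other 3 cadmium controls ran from 7.02 to 22.62, a gap of 0.854 of the range, above Dixon's limit for 4 arrays. It was 1 of 7 such comparisons, and chance passes that limit in about 1 of 20 groups. The responses to 4 exposures differed from the response to starving when the difference itself was tested: 177 probes for copper, 5 for cadmium, 2 for fluoranthene and 1 for Planktothrix. With 1 array left out at a time these counts ran from 98 to 490, 1 to 102, 2 to 28 and 0 to 16, with each highest count in the fit without full-food replicate 1. The single Planktothrix probe, CUST_16607_PI429715507, was 7.38 apart on the log2 scale, and its call was lost in 7 of 12 fits with 1 array left out.

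Most copper calls were increases in the main scaling, at 78.2% for the high level. The share stayed at 69.2% with slide as a block, which argues against slide differences as the reason. It was 32.6% without the 4 arrays with few probes detected, of which 1 was a copper control, and 36.1% after quantile normalization, so both that control and the scaling may account for the excess of increases. The fit without those arrays also recomputed the filter and the scaling, over 3014 probes in place of 679. In it 10.8% of the risen probes were called again, their median log2 change going from 1.86 to 1.07. Their median SE was 0.53 before and 0.49 after, so those calls ended because the change shrank. Whether the control or the new scaling shrank it cannot be told apart in that fit. Of the fallen probes 92.7% were called again, with a median of -2.81 before and -3.17 after, which argues against that control as their source. Scaling shifts all probes of an array alike, and the fallen probes changed by a median of -3.37 relative to all tested probes. That argues against the scaling as their source, and 292 probes were still called lower after quantile normalization. An effect of copper is left as a hypothesis, with background handling and other array differences still open, since 75 of the falls were called in all 10 alternatives counted above.

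The fluoranthene high response resembled starving, with a correlation across probes of 0.476, inside the range of -0.521 to 0.51 that simulations without a true effect gave. Without slide 6, which held 2 of the 3 arrays of each group, it was 0.105, and with slide as a block it was 0.136. A difference of that slide may therefore explain the resemblance, as may the noise that the simulations carry. The fit without slide 6 leaves 1 starving and 1 fluoranthene high array, so its value is noisy. A shared biological response to low food intake stays open, since with 2 of the 3 arrays of each group on slide 6 both fits can also remove part of such a response.

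The cadmium groups hold 4 controls and 2 low-level arrays where other groups hold 3, so a low-level array labelled as a control was tested. On a line from the other controls at 0 to cadmium high at 1, control replicate 5 lay at 0.63, near the low-level arrays at 0.69 and 0.73, while the other controls lay between -0.03 and 0.08. That met what had been written in advance for a wrong label, and its fallen probes lay at -0.09, but neither value decides, because 24 of 25 risen probes lie under that array's lowest signal above background in the other controls and 18 of 25 fallen probes do in cadmium high. On probes readable on that array, over 6 choices of probes, its position lay above 0.5 in 5, at up to 0.78, and at 0.03 in the form with the most probes, while the other controls ran from -0.15 to 0.27 and the low-level arrays from 0.46 to 0.97. The lower ends of its bootstrap 95% intervals ran from -0.35 to 0.22 and the upper ends from 0.48 to 0.96, so a wrong label and a raised signal floor both stay open, and no biological explanation was tested.

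Regroupings of the same arrays were fitted in the same way. For cadmium high, 3 of 35 splits gave at least as many probes as the real 80, the highest other giving 660, so that count alone does not exclude chance. Both other splits, with 660 and 199, set control replicate 5 on the side of cadmium high arrays, and the one with 660 is the real grouping with that array alone moved. Chance cannot be excluded either for the effects set against starving, in 100 splits drawn for each: 14 reached the real 5 for cadmium (highest other 5294), 18 the real 177 for copper (2647), 20 the real 1 for Planktothrix (3425) and 21 the real 2 for fluoranthene (4018). For cyhalothrin the real count was 0, which all 100 splits reach whatever they hold, so they decide nothing (highest other 2562). For the 4 controls 13 of 100 reached the real 617, with 3986 as the highest other. Splits that call many times the real count point to a structure among the arrays that the groups do not follow.

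With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real count and the highest other were 1692 and 2 for copper high, 1903 and 357 for copper low, 64 and 0 for fluoranthene high, 3 and 0 for cyhalothrin low and 5 and 0 for fluoranthene high against low. In each of these 5 comparisons 1 split, the real one, reached the real count. All 10 splits reached the real count of 0 for Planktothrix high (highest other 0), Planktothrix low (115), cyhalothrin high (0), fluoranthene low (0) and the level comparisons of copper (0), Planktothrix (0), cyhalothrin (1585) and starving against half-food (0). For half-food 3 splits reached the real 1, with 1008 as the highest other. For starving 2 splits reached the real 33, and the other, with 3976, set the 3 arrays of slide 6 against the rest, while slide as a block gave 35 for the real groups.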

How the results depend on the processing

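Chosen after seeing the data were array weights, scaling to all probes, the fits without the 4 low-detection arrays or slide 6 or both, and every value reported for them here. The values below are numbers of probes past the threshold unless called a correlation, and are given where a count moved by over 1.5 times. No comparison of named probes changed direction under any alternative, and the series table kept all 29 results within that range. Where no reason is given, the cause was not tested. The 4 copper probes named in the report and CUST_14595_PI429715507 with cadmium stayed past the threshold in every alternative, single arrays left out included. The other named probes fell below it in at least 1, most often CUST_2126_PI429715507 in cyhalothrin low, in 13 of 18, with adjusted p from 1.34e-05 to 0.323. With 1 array left out, 100 of 124 tests of named probes stayed past the threshold and 24 did not. Planktothrix against control stayed at 0 under each of the 12 whole-set alternatives.

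Background, scaling and filter moved between 8 and 15 of the 29 results. Normexp correction gave 50 for cadmium high, 430 for copper high, 353 for copper low and 1 for cyhalothrin low. It gave 24 for fluoranthene high, 18 for starving, 3 for half-food and 111 for the 4 controls. Quantile normalization gave 159 for cadmium high, 44 for cadmium low, 457 for copper high, 467 for copper low, 3 for fluoranthene low and 19 for starving. It gave 8 for fluoranthene high against low, 2 for starving against half-food, 49 for cadmium against the starving effect, 82 for copper against the starving effect, 6 for fluoranthene against the starving effect and 6 for the 4 controls. Scaling to all probes gave 134 for cadmium high, 34 for cadmium low, 270 for copper high, 215 for copper low and 0 for cyhalothrin low. It gave 9 for fluoranthene high, 1 for fluoranthene low, 13 for starving, 0 for half-food and 0 for fluoranthene high against low. There were 2 for starving against half-food, 21 for cadmium against the starving effect, 12 for copper against the starving effect, 0 for Planktothrix against the starving effect and 14 for the 4 controls. Testing all probes without the filter gave 26 for cadmium high, 6 for cadmium low, 175 for copper high, 135 for copper low, 0 for cyhalothrin low, 12 for fluoranthene high and 1 for starving. It gave 0 for half-food, 0 for fluoranthene high against low, 1 for cadmium against the starving effect, 40 for copper against the starving effect, 0 for Planktothrix against the starving effect, 0 for fluoranthene against the starving effect and 2 for the 4 controls. Without the filter 51424 probes shared the adjustment in place of 12872.

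The model moved between 7 and 20 of them. Fitting the arrays of each experiment alone, with fewer arrays behind the spread, gave 8 for cadmium high, 0 for cadmium low, 39 for fluoranthene high, 1 for fluoranthene low and 3 for starving. It gave 0 for half-food, 0 for fluoranthene high against low, 2 for cadmium against the starving effect, 5 for fluoranthene against the starving effect and 0 for the 4 controls. Slide as a block gave 1242 for copper low, 37 for fluoranthene high, 22 for half-food, 2 for fluoranthene high against low, 4 for fluoranthene against the starving effect, 1549 for the 4 controls and 0.136 for the fluoranthene correlation with starving. The replicate number as a block, a pairing that the arrays did not bear out, gave 27 for cadmium high, 266 for copper high, 848 for copper low, 28 for fluoranthene high, 4208 for starving and 279 for half-food. It gave 0 for fluoranthene high against low, 1306 for cadmium against the starving effect, 551 for copper against the starving effect, 728 for Planktothrix against the starving effect, 2447 for cyhalothrin against the starving effect and 345 for fluoranthene against the starving effect. Array weights gave 2503 for cadmium high, 297 for cadmium low, 31 for cyhalothrin high, 2379 for cyhalothrin low, 4337 for fluoranthene high, 12 for fluoranthene low and 7353 for starving. It gave 3008 for half-food, 47 for cadmium high against low, 7 for copper high against low, 1 for Planktothrix high against low, 466 for cyhalothrin high against low, 5666 for fluoranthene high against low and 6717 for starving against half-food. There were 3661 for cadmium against the starving effect, 3386 for copper against the starving effect, 2746 for Planktothrix against the starving effect, 5580 for cyhalothrin against the starving effect, 2568 for fluoranthene against the starving effect and 3188 for the 4 controls. The weights ran down to 0.06 for cadmium control replicate 5, and were estimated from the same few arrays per group that the counts rest on. Starving replicates 2 and 5, on slide 6, had weights of 4.32 and 3.03, against 0.17 for replicate 4. Fluoranthene high replicates 2 and 5, also on slide 6, had 3.6 and 1.18, against 0.36 for replicate 4. Full-food replicate 1, on the same slide, had 0.14. Weighted counts that use starving or fluoranthene high thus largely set slide 6 against other slides. They cannot separate the exposure from that slide. Cyhalothrin low replicates 1 and 3 had weights of 6.53 and 5.71, against 0.09 for replicate 4, so the weighted count of that group rests mostly on those 2 arrays.

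Leaving out sets of arrays changed the scaling and the filter as well, with 14087 probes tested without the 4 low-detection arrays, 14595 without slide 6 and 15252 without both. The fit without the 4 low-detection arrays gave 406 for cadmium high, 71 for cadmium low, 816 for copper high, 816 for copper low, 4 for cyhalothrin high and 18 for cyhalothrin low. It gave 217 for fluoranthene high, 4 for fluoranthene low, 115 for starving, 304 for half-food, 1 for cadmium high against low and 44 for fluoranthene high against low. There were 27 for starving against half-food, 35 for cadmium against the starving effect, 12 for cyhalothrin against the starving effect, 15 for fluoranthene against the starving effect and 1134 for the 4 controls. Without slide 6, which leaves 1 array each for starving and fluoranthene high, there were 1 for fluoranthene high, 4 for starving, 734 for half-food, 0 for fluoranthene high against low, 12 for starving against half-food and 2 for cadmium against the starving effect. It gave 64 for copper against the starving effect, 0 for Planktothrix against the starving effect, 1 for fluoranthene against the starving effect, 2050 for the 4 controls and 0.105 for the fluoranthene correlation with starving. The fit without both gave 448 for cadmium high, 101 for cadmium low, 1095 for copper high, 1266 for copper low, 21 for cyhalothrin low, 39 for fluoranthene high and 3 for fluoranthene low. It gave 76 for starving, 2624 for half-food, 1 for cadmium high against low, 12 for fluoranthene high against low, 132 for starving against half-food, 20 for cadmium against the starving effect and 316 for copper against the starving effect. There were 10 for Planktothrix against the starving effect, 14 for cyhalothrin against the starving effect, 12 for fluoranthene against the starving effect, 3349 for the 4 controls and 0.105 for the fluoranthene correlation with starving.

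With 1 array left out at a time, counts ran from 40 to 230 for cadmium high, 5 to 59 for cadmium low, 383 to 2892 for copper high, 391 to 3004 for copper low and 0 to 817 for Planktothrix high. They ran from 0 to 1471 for Planktothrix low, 0 to 5 for cyhalothrin low, 29 to 60 for fluoranthene high, 2 to 1878 for starving and 0 to 498 for half-food. The range was 0 to 45 for cadmium high against low, 0 to 7 for fluoranthene high against low, 1 to 102 for cadmium against the starving effect, 98 to 490 for copper against the starving effect and 0 to 16 for Planktothrix against the starving effect. Ranges were 0 to 575 for cyhalothrin against the starving effect, 2 to 28 for fluoranthene against the starving effect and 3 to 1766 for the 4 controls. The count stayed at 0 for cyhalothrin high, fluoranthene low, copper high against low, Planktothrix high against low, cyhalothrin high against low and starving against half-food. The highest values for starving, half-food, the 4 controls and all 5 effects set against starving came without full-food replicate 1, which lay on slide 6. The highest for copper and Planktothrix against control came without their control replicate 5. Where 1 array was left in a group, it was assumed to vary like the other groups. The correlations with starving were given the same treatment, and the jackknife error was 0.21 for fluoranthene and 0.40 for cadmium.

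Signal over background limited the tests, since 25% of the probes passed the filter and 1 array had 2.23% of probes well above background. The gene lists and their estimated correlation between genes were planned and not run, because no probe was joined to a gene.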

Other observations

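Chosen after the result was seen were the test of the sizes of the copper changes and the simulated values without a true effect. The tests of the number of arrays and of the cadmium probes in other exposures were fixed before their values were seen.

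Some probes changed in several exposures. CUST_36222_PI429715507 rose past the threshold with cadmium and copper at both levels, with cyhalothrin low and with fluoranthene high, by log2 changes from 3.10 to 4.55, and its change with starving was -1.14 (adjusted p 0.266). Those 6 comparisons rest on 3 control groups. CUST_76717_PI429715507, named for its rise with starving, also rose with cadmium high by 5.77 and with copper high by 3.64. CUST_101160_PI429715507 fell with fluoranthene high by -5.03 and with starving by -3.27. Slide 6 held 2 of the 3 arrays of each of those groups. The fluoranthene change ran from -5.77 to -4.65 over 18 alternatives, the fit without slide 6 among them, where 1 exposed array was left. The starving change of this probe was not tested that way.

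The probes called in cadmium high and copper high overlapped in the same direction more than independent lists would under each setting tried. The shared number was 46 where independence gives 6.4, 16 against 0.8 with normexp correction, 29 against 2.2 with quantile normalization and 48 against 6.3 with slide as a block. It was 4 against 0.6 in the fits to each experiment alone. With array weights the excess was smaller in proportion, at 488 against 243.2, with 46 probes in opposite directions.

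No probe differed between copper high and copper low by limma, with 99 at an unadjusted p under 0.05. The labels give no copper concentration for either level. One hypothesis is that both levels gave the gut a similar exposure. Over the 2194 probes called at either level, the median size of the change at the low level was 1.005 times that at the high level, and 0.971 times without the 4 arrays with few probes detected, but this does not decide. Both levels use the same control arrays, and on as many probes with the smallest p-values 60 simulations without a true effect gave 95% of ratios between 0.235 and 3.107. Too few arrays may also explain the lack of calls, since 20.7% of simulated 4-fold changes between the levels were called.

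The 80 cadmium high probes were set against Planktothrix high, which gave no call of its own. Relative to all probes their median log2 change in the cadmium direction was 0.49, with quartiles of -0.30 and 1.02, where 60 simulations without a true effect gave 95% of medians between -0.37 and 0.26. Over 12 alternatives the median ran from 0.32 to 0.64. The 55 risen probes had a median change of 0.29 and the 25 fallen probes one of -0.76, so the fallen probes moved more. Risen and fallen probes were not simulated apart. Set against the mean of the controls, the 3 Planktothrix high arrays lay between 0.36 and 0.46 and the 3 control arrays between -0.53 and 0.26. With Planktothrix low the median was 0.39 (simulated range -0.28 to 0.35), from 0.16 to 0.54 over the alternatives. Its arrays lay at -0.15, 0.55 and 0.52. The first, replicate 2 with the raised floor, lay within the range of the controls. With Planktothrix low the risen probes had a median change of 0 and the fallen probes one of -1.12. The simulated ranges are approximate, since the noisier arrays did not stay in their groups. A response common to all stressors was tested as a hypothesis. The lowest median among starving, fluoranthene high and cyhalothrin high was 0.15, in cyhalothrin high, with 0.70 in starving and 0.80 in fluoranthene high, so the values reached neither the level set in advance for a common response nor the level set against it. The simulated range was -0.34 to 0.40 in cyhalothrin high, which holds its median, -0.24 to 0.43 in starving and -0.31 to 0.40 in fluoranthene high. Over the same alternatives the medians ran from 0.06 to 0.16 in cyhalothrin high, 0.45 to 0.94 in starving and 0.43 to 0.97 in fluoranthene high. The risen and fallen probes had medians of 0.16 and -0.15 in cyhalothrin high, 0.39 and -2.30 in starving and 0.19 and -1.73 in fluoranthene high. The 80 probes together moved by a median of 1.15 with copper high, with a range of 0.92 to 1.97. With copper low the median was 1.09, with a range of 0.78 to 1.27. Both copper values rest on the same 3 control arrays as the Planktothrix value.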
